A study of Rattus norvegicus with 7 samples.

How the data were processed

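Single-nucleus RNA was sequenced from archived kidneys of 4-week-old rats of the HSRA model, a rat line studied for nephron deficit and chronic kidney disease. The sample titles give 1 kidney for 3 libraries and 2 kidneys for 4 libraries, and these are called the 1-kidney and 2-kidney libraries here. The labels count 3 HSRA-S and 4 HSRA-C animals, the same numbers. Per the labels' protocols, nuclei came from a central section that held cortex and medulla, were captured with the 10x Genomics 3' chemistry, version 3.1, at a target of 5000 nuclei per sample, and all 7 libraries were sequenced as 1 pool on 2 occasions on an Illumina instrument. The share of cortex and medulla in each section is not given in the sources used here. The labels speak of animals, and each title carries its own number, so each library was taken as 1 animal. Replicate numbers follow the accession order and only name a library. The library names hold a set code, P1117 for 5 libraries and P1117B for 2-kidney replicates 3 and 4. What the code stands for is not given in the sources used here. Set P1117B holds no 1-kidney library, and every comparison was repeated without it, as 3 libraries against 2. The gene tests per class and in all retained nuclei were also repeated with the set as a term in the model. The group difference in that model rests on set P1117 as well, so these repeats are not separate checks.

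The deposited matrices hold whole-number UMI counts per gene and barcode, and Cell Ranger 7.0 is named in the submitters' processing notes. The genome build and annotation are not given in the sources used here, and no coordinates were used. Gene symbols and Ensembl identifiers were taken from the deposited feature tables, which list 25399 genes. In them 148 symbols belong to more than 1 gene, and such genes were kept apart by identifier. Reads of near-identical copies could be split between them by the authors' counting, so values of genes from multigene families such as the Cyp4a genes are uncertain to that extent. The files hold 37048 barcodes, a mean of 5292.57 per library beside 5293 in the labels. The mean of the library medians was 1179.71 genes per barcode, beside 1180 in the labels.

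Barcodes with at least 200 genes and at most 5% mitochondrial UMIs were kept. Doublet scores were computed per library with the Scrublet method in scanpy 1.11.5. Its automatic threshold marked at most 2 barcodes in any library, so it had not worked. Barcodes were therefore removed from the highest scores down to the score at the rank of the expected share, 0.8% per 1000 barcodes, a rule chosen after seeing the data. Ties at that score raised the share removed above the expected one in every library, at the most to 443 barcodes in 2-kidney replicate 3 (6.54% against 5.42% expected) and 250 in 1-kidney replicate 3 (5.00% against 4.00%). This left 31252 nuclei. Counts were scaled to 10000 per nucleus and log transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 gave 29 clusters. No batch integration was applied. A cluster was named from markers fixed before the data were examined when at least 3 of them were at least 2-fold above the other nuclei and its leading gene at least 4-fold. The 4-fold bound was set after seeing the data. It left 7 clusters unnamed, with 23.5% ± 6.39 (SD, n = 3) of the 1-kidney nuclei and 20.2% ± 3.79 (SD, n = 4) of the 2-kidney nuclei. These clusters held 49.1% of the UMIs, and the largest of them had a median of 9305 UMIs per nucleus and a median doublet score of 0.0917, so undetected doublets are open there. Slc34a1, a transcript of the proximal tubule, was at 192 to 316 per 10000 UMIs in 5 of them, beside 130 and 351 in the 2 proximal tubule clusters and 31.4 to 192 in the other 20 named clusters, where the lowest value was that of podocytes. Unnamed nuclei entered the sums over all retained nuclei. The other 22 clusters formed 15 classes, called by the usual cell type name and resting on markers alone. Comparisons used the 8 classes with at least 50 nuclei in every library. Cycling nuclei are a state and were compared for their share only.

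Raw counts were summed per library, over all retained nuclei and per class, since nuclei of 1 animal are not replicates. The sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment. A gene counted as changed at an adjusted p under 0.05. All log2 fold changes are 1-kidney over 2-kidney, with their standard error (SE). CPM are given as mean ± SD over 3 and 4 libraries. The test of a difference in effect between proximal tubule and thick ascending limb used both sums of each library, with the library as a block. The script was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Of the 4-fold changes it recovered 89% in all retained nuclei, 83% in podocytes, 85% in proximal tubule, 86% in thick ascending limb, 87% in distal convoluted tubule, 89% in connecting tubule, 78% in principal cells, 95% in intercalated cells and 90% in endothelium. Of the 2-fold changes it recovered 44%, 29%, 28%, 41%, 37%, 39%, 12%, 34% and 37% in the same order. Unchanged genes called in these runs numbered 7, 3, 11, 6, 4, 3, 3, 7 and 9, and with no change simulated it called 0 genes. The simulated genes varied independently, with no difference between library sets, in 1 run each. These counts therefore do not give the error rate in the real libraries.

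The 29 gene lists tested and the cell type markers were fixed before the data were examined. A list of 8 sex-linked genes was also fixed, as a technical check, and has no list test. Each list with at least 5 measured genes was tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move 1 way on balance, were run beside it. Named genes followed a rule fixed in advance. In all retained nuclei, proximal tubule and thick ascending limb these were the 10 changed genes with the largest fold in each direction, and in other classes 5. The rule required values that did not overlap between groups. It added up to 3 changed members per list, the 5 smallest p where fewer than 5 genes changed, and 18 kidney genes whatever their p. Some genes that this rule names are not reported here. Some list members that did not pass the test are given as examples and were chosen after their values were seen, among them Pax2, Insig1, Hmgcs1, Fkbp5 and Irs1.

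Shares of nuclei per class and 4 measures of library quality were compared with a two-sided exact permutation test of the difference of group means. The 35 splits of 7 libraries allow no p below 0.0286, and the 10 splits within set P1117 none below 0.1. Alternatives were size factors by RLE, DESeq2 1.42.0, no low-count filter, doublets kept, a mitochondrial limit of 10%, equal numbers of nuclei per library, classes by marker score, other clusterings, and leaving out each library in turn. Added after seeing the data were sums over named clusters only, each proximal tubule cluster alone, shares among named nuclei, and quality measures without set P1117B. Copies of 1 library under 2 names were looked for over the 21 library pairs. The lowest chi-square per gene was 13.9 and no pair shared more than 14 barcodes, so all 7 were used. Pairs across the 2 library sets differed most (83.6 to 144), beside 13.9 to 40.9 within set P1117 and 31.6 within set P1117B, so the libraries differed more by set than by number of kidneys, in a measure that grows with depth. Ambient RNA was not subtracted, since only barcodes called as nuclei were used. Counts of proximal tubule genes and of the proximal tubule transport list in other classes therefore include free RNA to an unknown extent. The same holds for the fatty acid oxidation and gluconeogenesis lists, which share Slc27a2 and Fbp1 with the proximal tubule markers. Free RNA of the other classes was not subtracted either.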

Results

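The data are 7 single-nucleus RNA libraries from kidneys of 4-week-old HSRA rats, 3 from 1-kidney and 4 from 2-kidney animals. The design asks how the cells of the 1-kidney animals differ from those of the 2-kidney animals. Retained nuclei numbered 2270, 4427 and 4313 in 1-kidney replicates 1 to 3, with 5617523, 16291358 and 18159607 UMIs. The 2-kidney replicates 1 to 4 gave 3962, 4440, 5898 and 5942 nuclei with 15162199, 17001243, 24917489 and 26813318 UMIs. The median nucleus held 1712 ± 260 UMIs in the 1-kidney and 2186 ± 255 in the 2-kidney libraries (SD, n = 3 and 4, exact permutation p = 0.0857, adjusted p = 0.171). Median genes per nucleus were 1111 ± 151 and 1334 ± 108 (exact permutation p = 0.0857). Retained nuclei were 3670 ± 1214 and 5061 ± 1012 (p = 0.229, exact permutation test) and the mitochondrial share of UMIs 1.19% ± 0.432 and 0.958% ± 0.530 (p = 0.543, exact permutation test). The 2 libraries of set P1117B had the lowest mitochondrial shares (0.647% and 0.372%), and within set P1117 the difference had the opposite sign (−0.215 percentage points, exact permutation p = 0.6). None of these 4 measures passed the threshold, and within set P1117 the p for median UMIs was 0.3 by the same exact test.

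Nuclei with markers of the connecting tubule, the segment where calcium and sodium uptake are regulated, made up 5.16% ± 0.997 of the 1-kidney and 3.49% ± 0.429 of the 2-kidney nuclei (SD, n = 3 and 4). Acid-base regulating intercalated cells made up 6.30% ± 0.651 and 5.32% ± 0.462. In both classes all 3 of the 1-kidney libraries lay above all 4 of the 2-kidney libraries (exact permutation p = 0.0286 each, the smallest possible). Cycling nuclei, marked by Mki67 and Top2a, made up 3.52% ± 0.684 and 2.03% ± 0.555 (exact permutation p = 0.0857). Distal convoluted tubule made up 5.76% ± 0.962 and 4.14% ± 0.823 and thin limb 1.66% ± 1.31 and 3.55% ± 0.922 (exact permutation p = 0.0857 each). Proximal tubule made up 20.7% ± 3.52 and 22.6% ± 4.79, thick ascending limb 10.6% ± 3.04 and 11.7% ± 2.86 and principal cells 4.99% ± 2.12 and 6.11% ± 1.11. Endothelium made up 7.26% ± 1.90 and 9.10% ± 1.41 and podocytes 3.04% ± 0.821 and 3.45% ± 0.945. After adjustment over 15 classes no share differed (exact test, adjusted p = 0.214 for connecting tubule and intercalated cells), and at least 9 classes at the smallest possible p would have been needed for any to pass. The edgeR test on nuclei counts also gave 0 classes, with cycling nuclei (0.0174) and connecting tubule (0.0387) at an unadjusted p under 0.05 and intercalated cells not (0.261). Within set P1117 the exact p was 0.2 for connecting tubule and 0.1 for intercalated cells. 1-kidney replicate 2 held 10 thin limb nuclei, 0.226% of its nuclei. The share of cortex and medulla in the section was not measured and bears on every one of these shares.

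**Figure D1:**
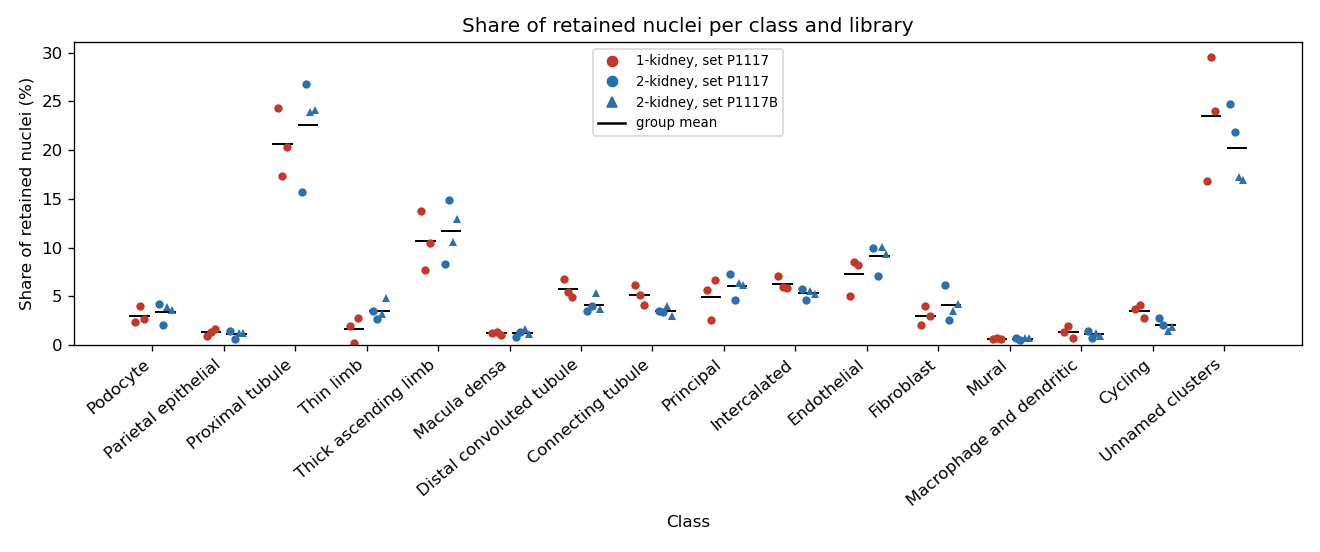
Share of retained nuclei (percent, vertical axis) in each class (horizontal axis), 1 point per library, with red for 1-kidney and blue for 2-kidney libraries, triangles for set P1117B and black lines for group means. Connecting tubule and intercalated shares of the 1-kidney libraries all lie above those of the 2-kidney libraries.

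Summed over all retained nuclei, genes of cholesterol synthesis, growth factor signalling, kidney development and extracellular matrix fell as lists in the 1-kidney libraries, and glucocorticoid response, unfolded protein response, fatty acid oxidation and cell cycle genes rose. These calls rest on the preset correlation, and all were lost with an estimated one (adjusted p = 0.645 to 0.803). Sums over all nuclei also follow the mix of classes, which was not separated from a change within cells. Fibroblasts made up 3.01% of the 1-kidney and 4.12% of the 2-kidney nuclei (exact permutation p = 0.343). With all 7 libraries the extracellular matrix list passed here and in none of the 8 classes. Of 24 cholesterol synthesis genes 21 had a fold below 0, with a median log2 fold of −0.41 (camera adjusted p = 0.0011, 0.744 with an estimated correlation). Growth factors and receptors had a median of −0.32, and 5 of 31 members a fold above 0 (camera adjusted p = 0.00306, 0.645 with an estimated correlation). Among them were Fgfr2, a receptor for fibroblast growth factors, at −1.10 ± 0.16 (SE, 30.4 ± 5.59 CPM against 65.5 ± 7.77), and Igf1, a growth hormone target, at −1.19 ± 0.24. Of the 56 development genes 19 had a fold above 0 (median −0.22, camera adjusted p = 0.00306, 0.645 with an estimated correlation), and Pax2, a transcription factor of nephron formation, stood at −0.98 ± 0.19. Glucocorticoid response genes had a median of 0.34 (12 of 14 above 0, camera adjusted p = 0.00306, 0.744 with an estimated correlation), with Pdk4, a brake on pyruvate oxidation, at 1.82 ± 0.32.

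The unfolded protein response list had a median of 0.37 (19 of 22 above 0, camera adjusted p = 0.00238), with Creld2 at 1.09 ± 0.20, fatty acid oxidation 0.15 (24 of 34, adjusted p = 0.0169) and cell cycle 0.25 (31 of 43, adjusted p = 0.0105), all 3 lost at 0.803 with an estimated correlation. Extracellular matrix had a median of −0.36 (7 of 43 above 0, adjusted p = 0.00306) and angiogenesis and endothelium −0.32 (5 of 25, adjusted p = 0.0144), both also lost at 0.803. Within set P1117 8 of these 9 calls held, and cell cycle did not (adjusted p = 0.116). Adjusted over the list alone, 14 development genes passed as lower and 1 as higher. By the same measure 3 growth factor genes, 2 matrix genes and 1 cholesterol gene passed as lower, and 6 fatty acid oxidation, 3 glucocorticoid and 3 unfolded protein genes as higher. Such counts, here and below, are no separate support. They are given only for lists that passed in the same libraries. Of all 14933 genes 3082 had an unadjusted edgeR p under 0.05, and other lists are not set beside them. Markers of thin limb (median −0.80), fibroblasts (−0.84), podocytes (−0.34), thick ascending limb (−0.31) and principal cells (−0.37) were lower and cycling markers (0.67) higher over the same sums (camera adjusted p = 3.81e-05 to 0.0311). Those 6 marker calls were also lost with an estimated correlation (adjusted p = 0.296 to 0.629).

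No single gene of 14933 passed in all retained nuclei with edgeR (smallest adjusted p = 0.154). At an unadjusted p under 0.05 there were 3082, and DESeq2 called 475. Within set P1117, and with the set as a term, the count was also 0. The genes with the smallest p after Fgfr2 were Efcab5 at 0.92 ± 0.14 (SE), the collagen gene Col24a1 at 1.29 ± 0.20, the phosphatase gene Ptpn14 at −0.85 ± 0.13 and Np4 at 1.54 ± 0.24 (adjusted p = 0.154 each). Of the kidney genes fixed in advance, the injury marker Havcr1 stood at 1.43 ± 0.42 (1.08 ± 0.470 CPM against 0.406 ± 0.122, adjusted p = 0.181). Umod, which encodes uromodulin, stood at −0.59 ± 0.18 and Kit at −0.75 ± 0.18. Egf was at 0.42 ± 0.23 and Slc12a1 at −0.31 ± 0.25. Slc12a3 was at 0.20 ± 0.17, Slc5a2 at 0.37 ± 0.31, Aqp2 at −0.38 ± 0.32, Pck1 at 0.24 ± 0.21 and Vcam1 at −0.35 ± 0.38. Kitlg (−0.06), Nphs1 (−0.07) and Spp1 (0.04) lay within 1 SE of 0. Lcn2 was too low to be tested.

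In proximal tubule nuclei, which reabsorb most of the filtrate, immediate early and heat shock genes and glucocorticoid response genes rose as lists in the 1-kidney libraries at the preset correlation. The first list had a median log2 fold of 0.43 (15 of 20 above 0, camera adjusted p = 0.0105, 0.79 with an estimated correlation), with the chaperone gene Hsp90ab1 at 0.91 ± 0.20 (SE). The second had a median of 0.45 (8 of 13 above 0, camera adjusted p = 0.0243, also 0.79 with an estimated one), with Pdk4 at 1.44 ± 0.30 and Tsc22d3, a glucocorticoid-induced gene, at 0.97 ± 0.25. Within set P1117 both calls held (adjusted p = 0.0309 and 0.000182). Adjusted over the list alone, 4 and 2 members passed as higher. Lower values were seen for Folh1, a carboxypeptidase gene, at −1.08 ± 0.17 (86.9 ± 8.72 CPM against 184 ± 29.8), and the tight junction gene Cldn10 at −1.07 ± 0.20. The amino acid transporter Slc43a2 stood at −1.51 ± 0.27, Kcp at −1.46 ± 0.25 and Cpeb3 at −0.80 ± 0.15. None of these 5 passed the threshold (adjusted p = 0.237 each). Thin limb markers were lower in this class (median −0.58, 0 of 6 above 0, camera adjusted p = 0.0106, 0.29 with an estimated correlation).

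No gene of 10859 passed in proximal tubule with edgeR, 1822 had an unadjusted p under 0.05, and DESeq2 called 115. Within set P1117 edgeR called 3 genes, all lower, Folh1 among them (adjusted p = 0.0267). The class joins a cluster high in Slc7a13, a transporter of the straight segment, and a cluster high in Slc5a12, a transporter of the convoluted segment. The Slc5a12 cluster held 17.8% ± 1.73 of proximal tubule nuclei in the 1-kidney and 41.2% ± 13.9 in the 2-kidney libraries (SD, n = 3 and 4, exact permutation p = 0.0571). Within set P1117 the 2-kidney mean was 30.4% and the exact p 0.1, the smallest possible. Among the unnamed clusters, 5 held the phosphate transporter transcript Slc34a1 at 192 to 316 per 10000 UMIs, beside 130 and 351 in these 2 clusters and 31.4 to 192 in the other 20 named clusters. Clusters with as much of this transcript as the class itself were thus left outside it, and the transcript was counted in every named cluster. Each cluster alone gave 0 genes with edgeR, with 1495 and 952 at an unadjusted p under 0.05 and 77 and 33 by DESeq2. Within set P1117 the counts were 7 in the Slc7a13 cluster and 6 in the Slc5a12 cluster. In the Slc7a13 cluster Slc5a12 itself stood at 1.29 ± 0.22 and the bicarbonate transporter Slc4a4 at 1.02 ± 0.18. Cpeb3 was at −1.07 ± 0.16 and Sv2c at 2.17 ± 0.40 (adjusted p = 0.187 to 0.191). In the Slc5a12 cluster Pdk4 stood at 2.02 ± 0.38, Idh3g at 1.16 ± 0.24 and Efcab5 at 0.86 ± 0.18, while Slc43a2 was at −1.11 ± 0.21 (adjusted p = 0.252 each). Glucocorticoid response rose as a list in both (camera adjusted p = 0.0072 and 0.000323, 0.81 and 0.474 with an estimated correlation), as did unfolded protein response (adjusted p = 0.00456 and 0.00157, lost at 0.81 and 0.569).

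In thick ascending limb nuclei, the segment that dilutes the urine, Slc5a12 (ENSRNOG00000028008), a lactate transporter of the proximal tubule, was counted 2.63-fold higher in the 1-kidney libraries (log2 fold 1.39 ± 0.19 SE, 284 ± 70.2 CPM against 109 ± 8.66, edgeR adjusted p = 0.0166). Free RNA was not subtracted, and Slc5a12 stood at 1.78 and 1.47 per 10000 UMIs in the 2 thick ascending limb clusters, beside 0.915 in the Slc7a13 and 10.3 in the Slc5a12 cluster of proximal tubule, so a change within these nuclei is not shown for this gene. Sema6d (ENSRNOG00000004812), a semaphorin, fell to 0.387 of its 2-kidney level (−1.37 ± 0.23) and the ephrin receptor Ephb2 (ENSRNOG00000012531) to 0.450 (−1.15 ± 0.19; adjusted p = 0.0458 each). Growth factors and receptors (median −0.28) and cholesterol synthesis (median −0.62, 0 of 11 above 0) fell as lists, and fatty acid oxidation (0.25), cell cycle (0.70), proximal tubule transport (0.35), unfolded protein response (0.38) and glucocorticoid response (0.32) rose, with camera adjusted p = 0.000197 to 0.00367. These 7 calls were lost with an estimated correlation (adjusted p = 0.441 to 0.567), and within set P1117 all 7 held (adjusted p = 1.6e-07 to 0.0330). The insulin receptor substrate Irs1 stood at −1.30 ± 0.26 and Fgfr2 at −1.11 ± 0.25, and adjusted over the list alone 6 growth factor genes passed as lower. Pdk4 stood at 1.72 ± 0.32, the mineralocorticoid and glucocorticoid target Sgk1 at 1.04 ± 0.25 and the collagen gene Col27a1 at 2.68 ± 0.49. None of these 3 passed the threshold (adjusted p = 0.0673 for Pdk4 and Col27a1, 0.118 for Sgk1).

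All 15 measured proximal tubule markers had a fold above 0 in thick ascending limb (median 0.50, camera adjusted p = 3.6e-06, 0.315 with an estimated correlation). Slc5a12, the gene with the smallest p, is one of them. Of 7797 genes 3 changed in thick ascending limb, 1 up and 2 down. With RLE factors 1 gene passed, as higher, and with DESeq2 64. Classes by marker score gave 0 and predicted doublets kept gave 1. With the library set as a term 11 passed and within set P1117 15, Slc5a12, Sema6d and Ephb2 among the 15. Left out in turn, 1-kidney replicates 1 to 3 gave 1, 0 and 0 genes and 2-kidney replicates 1 to 4 gave 115, 26, 0 and 13.

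**Figure D2:**
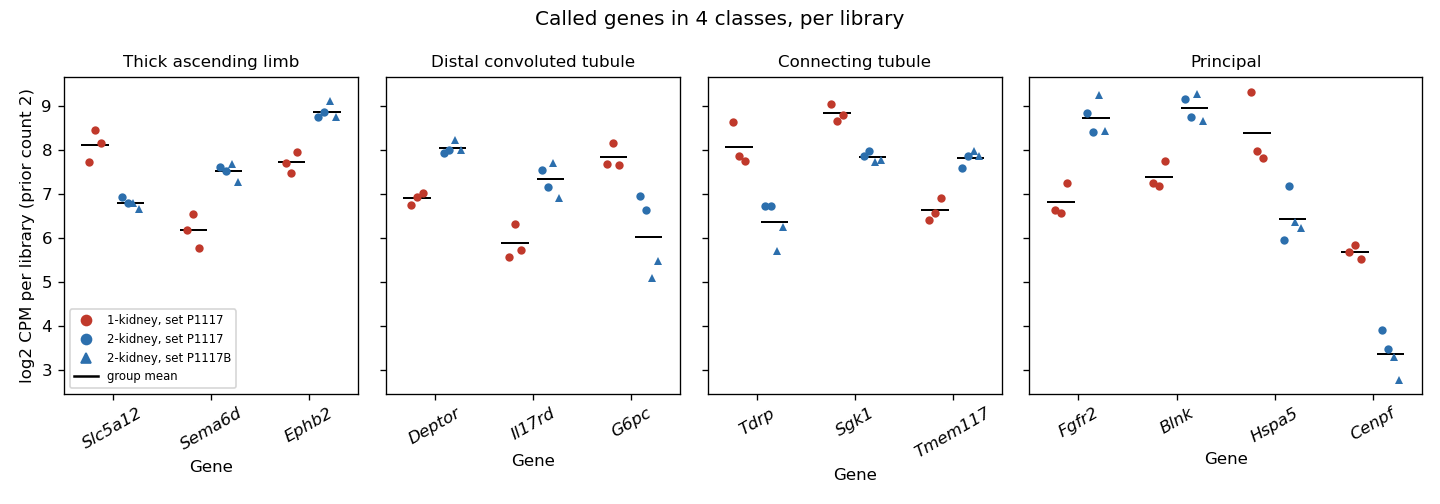
Log2 CPM per library (vertical axis, prior count 2) of 13 changed genes (horizontal axis) in 4 classes, with red for 1-kidney and blue for 2-kidney libraries, triangles for set P1117B and black lines for group means. The groups do not overlap for any gene shown, as the rule for naming them required.

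The difference between the groups was itself tested between proximal tubule and thick ascending limb. In 33 of 10488 genes the 1-kidney effect differed, 30 with the lower effect in proximal tubule and 3 with the higher (edgeR adjusted p under the threshold, 947 genes at an unadjusted p under 0.05). The amino acid transporter Slc6a19 stood at −0.36 in proximal tubule and 1.06 in thick ascending limb (difference −1.45 ± 0.23 SE, adjusted p = 0.00907). The dicarboxylate transporter Slc13a3 stood at −0.91 and 0.40 (−1.32 ± 0.23, adjusted p = 0.0136), and Slc5a12 at 0.01 and 1.39 (−1.35 ± 0.24, adjusted p = 0.0160). In the Slc7a13 cluster alone, as given above, Slc5a12 was higher by nearly as much as in thick ascending limb. Its value near 0 in the whole class also follows the mix of the 2 clusters, so a differing effect is not shown for Slc5a12. Col27a1 had 0.79 and 2.68 (−1.92 ± 0.27, adjusted p = 0.00262) and the transcription factor gene Etv1 −0.20 and 1.65 (−1.83 ± 0.30). Of the 30 genes 28 were more abundant in proximal tubule than in thick ascending limb, as were 4054 of all 10488. Without set P1117B 3 genes remained past the threshold. With the Slc7a13 cluster in place of the whole proximal tubule class 3 genes passed, which need not be among the 33. Left out in turn, 1-kidney replicates 1 to 3 gave 25, 1 and 0 genes and 2-kidney replicates 1 to 4 gave 169, 31, 15 and 1.

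In distal convoluted tubule nuclei, where thiazide-sensitive salt uptake takes place, Deptor, Il17rd, Casz1 and Mtmr7 fell in the 1-kidney libraries, and Ptger3 was counted at a lower level. Transcripts of the proximal tubule genes G6pc, Khk, Slc5a12 and Slc4a4 were counted at higher levels, with free RNA not subtracted and Slc34a1 at 53.3 per 10000 UMIs in this class, so a change within these nuclei is not shown for them. G6pc (ENSRNOG00000051171), the last enzyme of glucose release, was 3.54-fold higher (log2 fold 1.82 ± 0.34 SE, 228 ± 48.3 CPM against 70.2 ± 43.1), the fructose kinase gene Khk 2.61-fold, Slc5a12 2.63-fold and Slc4a4 1.98-fold. The fatty acid hydroxylase gene Cyp4a8 was counted 2.29-fold higher, with free RNA of proximal tubule not subtracted. The methionine sulfoxide reductase gene Msrb1 was 2.81-fold higher and Fam133b 2.30-fold. Deptor (ENSRNOG00000004328), an inhibitor of mTOR, fell to 0.450 of its 2-kidney level (−1.15 ± 0.22, 116 ± 11.2 CPM against 260 ± 24.1), and Il17rd, which restrains FGF signalling, to 0.358. Casz1 fell to 0.396 and the phosphatase gene Mtmr7 to 0.354. The prostaglandin receptor gene Ptger3 was counted at 0.429 of its 2-kidney level. Ptger3 is also a marker of thick ascending limb, whose free RNA was not subtracted, so a change within these nuclei is not shown for it. These adjusted p lay between 0.0395 and 0.0483 (edgeR). The proximal tubule transport list rose (median 0.52, 32 of 36 above 0, camera adjusted p = 8.57e-06, 0.532 with an estimated correlation). So did glucocorticoid response (0.65), gluconeogenesis (0.34), mitochondrial genome (0.32), immediate early and heat shock (0.44) and unfolded protein response (0.24), and growth factors and receptors fell (−0.32), with adjusted p = 0.0159 to 0.0307.

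The 7 list calls in distal convoluted tubule were lost with an estimated correlation (adjusted p = 0.532 to 0.713). Within set P1117, proximal tubule transport, unfolded protein response and glucocorticoid response held (adjusted p = 0.00313 to 0.0160), and the mitochondrial genome list turned to lower (adjusted p = 0.202). Adjusted over the list alone, 8 transport, 4 glucocorticoid, 1 gluconeogenesis, 1 immediate early and 1 unfolded protein genes passed as higher and 3 growth factor genes as lower. All 15 measured proximal tubule markers had a fold above 0 in this class (median 0.77, camera adjusted p = 7.4e-07, 0.234 with an estimated correlation). The markers of distal convoluted tubule itself (median −0.55, adjusted p = 0.0313), thick ascending limb (−0.64, adjusted p = 0.00141) and thin limb (−0.58, adjusted p = 0.00585) were lower. Those 3 marker calls were lost too with an estimated correlation (adjusted p = 0.11 to 0.234). In all, 14 of 6337 genes changed in distal convoluted tubule, 8 up and 6 down. Within set P1117 5 passed, 0 of the 14 among them. With the set as a term, with equal numbers of nuclei and with classes by marker score 0 passed. All 14 kept their direction within the set, at an unadjusted p under 0.05. This is no separate support, since their values did not overlap between the groups and the libraries of the set are part of the full comparison. Left out in turn, 1-kidney replicates 1 to 3 gave 2, 0 and 0 genes and 2-kidney replicates 1 to 4 gave 232, 4, 0 and 15.

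In connecting tubule nuclei the glucocorticoid response list rose with the highest median among the 9 comparisons of all 7 libraries. Within set P1117 its median of 0.696 lay below those of podocytes (0.784) and intercalated cells (0.705). With all 7 libraries the median log2 fold of this list was 0.92, and all 11 members had a fold above 0. Camera gave an adjusted p of 7.47e-06, and 0.422 with an estimated correlation, and 7 members passed when adjusted over the list alone. Sgk1 (ENSRNOG00000011815), a kinase that raises sodium channel activity, rose 2.03-fold (1.02 ± 0.17 SE, 459 ± 64.9 CPM against 225 ± 17.2, edgeR adjusted p = 0.0294). Fkbp5, a glucocorticoid receptor co-chaperone, stood at 1.32 ± 0.31 (adjusted p = 0.0862, and 0.000119 within set P1117). The set leaves out 2-kidney replicate 4, whose log2 CPM of 7.91 for Fkbp5 lay closest to the 1-kidney libraries (8.27 to 8.56). Tdrp (ENSRNOG00000027245) rose 3.43-fold (279 ± 101 CPM against 81.3 ± 26.1, adjusted p = 0.0133) and the imprinted gene Peg3 2.20-fold. G6pc was counted 3.17-fold higher, Cyp4a8 2.21-fold and Slc5a12 1.98-fold, with free RNA of proximal tubule not subtracted. Tmem117 fell to 0.432 of its 2-kidney level (−1.21 ± 0.20), Ppp2r2b, a regulatory subunit of protein phosphatase 2A, to 0.422 and Stxbp6 to 0.385 (adjusted p = 0.0294 to 0.0445).

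Fatty acid oxidation (median 0.32, 23 of 30 above 0, camera adjusted p = 0.00444) and mitochondrial genome (0.41, adjusted p = 0.0388) also rose as lists in connecting tubule. Both were lost with an estimated correlation (adjusted p = 0.659 and 0.799). Slc27a2 of the first list is also a proximal tubule marker, at 0.85 in this class, and free RNA was not subtracted. Within set P1117 glucocorticoid response and fatty acid oxidation held (adjusted p = 5.77e-07 and 5.24e-06), and the mitochondrial genome list was lower (adjusted p = 0.0417). Of 15 proximal tubule markers 13 had a fold above 0 in this class (median 0.46, camera adjusted p = 0.00193, 0.242 with an estimated correlation). In all, 15 of 6853 genes changed in connecting tubule, 12 up and 3 down, 3 of them without a gene symbol. Within set P1117 29 passed, 12 of the 15 among them, and with the set as a term 16. Left out in turn, 1-kidney replicates 1 to 3 gave 0, 0 and 6 genes and 2-kidney replicates 1 to 4 gave 80, 117, 1 and 18.

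In principal cells, which take up water and sodium in the collecting duct, the chaperone gene Hspa5 and the mitotic gene Cenpf rose and the growth factor receptor gene Fgfr2 fell in the 1-kidney libraries. Hspa5 (ENSRNOG00000018294), the main chaperone of the endoplasmic reticulum, rose 4.17-fold (log2 fold 2.06 ± 0.37 SE, 373 ± 234 CPM against 88.5 ± 37.8), Edem1, which sorts misfolded proteins for degradation, 3.65-fold, and Cenpf 6.33-fold (48.6 ± 5.59 CPM against 7.66 ± 3.43). Fgfr2 (ENSRNOG00000016374) fell to 0.265 of its 2-kidney level (−1.91 ± 0.28, 112 ± 31.6 CPM against 438 ± 127) and the adaptor gene Blnk to 0.340. The hedgehog co-receptor gene Boc fell to 0.330, Traf5 to 0.337 and the Golgi gene Cog5 to 0.345. Tsku rose 4.91-fold. The inositol transporter gene Slc5a11 was counted 3.25-fold higher, Cyp4a8 2.96-fold and Enpep, which encodes aminopeptidase A, 2.69-fold, with free RNA of proximal tubule not subtracted. The adjusted p of these 12 genes lay between 0.0341 and 0.0497 (edgeR). The unfolded protein response list rose (median 0.68, 16 of 18 above 0, camera adjusted p = 9.23e-05, 0.339 with an estimated correlation), with Hsp90b1 at 1.54 ± 0.35. So did cell cycle (0.81, 8 of 9), with Mki67 at 1.95 ± 0.57, and inflammation and NF-kB (0.86, 11 of 11), with the chemokine gene Cxcl16 at 1.77 ± 0.50. Both lists were also lost with an estimated correlation (adjusted p = 0.339 and 0.461). Hsp90b1, Mki67 and Cxcl16 did not themselves pass the threshold.

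Antigen presentation (median 0.83, 6 of 6 above 0), glucocorticoid response (0.69), fatty acid oxidation (0.34), mitochondrial genome (0.56), immediate early and heat shock (0.45) and proximal tubule transport (0.71, 38 of 43, camera adjusted p = 8.56e-09) also rose as lists in principal cells. The adjusted p of the 9 lists lay between 8.56e-09 and 0.0203, and all 9 were lost with an estimated correlation (adjusted p = 0.339 to 0.798). Within set P1117 unfolded protein response, glucocorticoid response, fatty acid oxidation, inflammation and proximal tubule transport held (adjusted p = 7.4e-07 to 0.000236). Adjusted over the list alone, 6 unfolded protein, 5 cell cycle, 5 fatty acid oxidation, 11 transport, 3 immediate early, 2 glucocorticoid, 1 antigen presentation and 1 inflammation genes passed as higher. All 15 measured proximal tubule markers had a fold above 0 in this class (median 0.98, camera adjusted p = 2.73e-08, 0.331 with an estimated correlation), with Cubn, an endocytic receptor gene, at 1.17 ± 0.24. Cycling markers were higher (1.80, adjusted p = 0.000358), and the 11 principal cell markers were all below 0 (median −0.60, adjusted p = 0.00425). The last 2 marker calls were also lost at 0.331. In all, 17 of 8514 genes changed, 10 up and 7 down. Within set P1117 and with the set as a term the count was 0. All 17 had the same direction at an unadjusted p under 0.05 within the set. That was all but fixed, since their values did not overlap between the groups and the set is part of the full comparison. With predicted doublets kept and with classes by marker score the count was also 0, with equal numbers of nuclei 40 and with DESeq2 208. Left out in turn, 1-kidney replicates 1 to 3 gave 0, 0 and 21 genes and 2-kidney replicates 1 to 4 gave 142, 97, 0 and 16.

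In podocytes, the filtering cells of the glomerulus, cholesterol synthesis genes fell as a list in the 1-kidney libraries, with a median log2 fold of −1.54 and 0 of 8 members above 0 (camera adjusted p = 6.33e-08, 0.508 with an estimated correlation, 1.72e-10 within set P1117). Insig1, a sensor of sterol levels, stood at −3.03 ± 0.68 (SE) and the synthase gene Hmgcs1 at −2.72 ± 0.67 (adjusted p = 0.179 and 0.209). Adjusted over the list alone, 5 of the 8 passed. Pla2g7 (ENSRNOG00000025691), a phospholipase that hydrolyses platelet-activating factor, rose 9.29-fold (3.22 ± 0.52, 56.0 ± 26.8 CPM against 6.06 ± 2.96, edgeR adjusted p = 0.0351). Unfolded protein response (0.45, with Hspa5 at 1.45 ± 0.33), glucocorticoid response (0.60) and proximal tubule transport (0.42) rose as lists (camera adjusted p = 0.00340 to 0.0313, lost with an estimated correlation at adjusted p = 0.39 to 0.89). The first 2 held within set P1117 (adjusted p = 0.000432 and 0.000128) and the last did not (adjusted p = 0.582).

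Kcnip1 at 2.13 ± 0.37, Fam189a1 at −1.93 ± 0.35, G6pc at 1.92 ± 0.36 and the natriuretic peptide clearance receptor gene Npr3 at −1.05 ± 0.21 did not pass in podocytes (adjusted p = 0.0507 to 0.0919). Free RNA of proximal tubule was not subtracted, which bears on G6pc. Nor was that of distal convoluted tubule, where Fam189a1 was among the leading genes of the cluster. Of 15 proximal tubule markers 14 had a fold above 0 in this class (median 0.49, camera adjusted p = 0.0123, 0.507 with an estimated correlation). Pla2g7 was the 1 changed gene of 6137, with 609 at an unadjusted p under 0.05 and 4 by DESeq2. None passed within set P1117 or with the set as a term. Left out in turn, 1-kidney replicates 1 to 3 gave 0, 1 and 1 genes and 2-kidney replicates 1 to 4 gave 143, 0, 0 and 9.

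In intercalated cells, glucocorticoid response genes rose as a list in the 1-kidney libraries, with a median log2 fold of 0.71 and all 10 members above 0 (camera adjusted p = 0.000179, 0.278 with an estimated correlation, 2.28e-06 within set P1117), and Sgk1 stood at 0.98 ± 0.23 (SE). Kidney development genes (median −0.21, 10 of 33 above 0) and growth factors and receptors (−0.33) fell (0.344 and 0.530 with an estimated correlation), with the receptor gene Kit, a marker of this class, at −1.02 ± 0.22. Fatty acid oxidation (0.16), gluconeogenesis (0.21), cytosolic ribosomal proteins (0.17), mitochondrial genome (0.39), proximal tubule transport (0.23) and unfolded protein response (0.25) rose. Camera gave these 8 lists an adjusted p of 0.00747 to 0.0354, lost with an estimated correlation (adjusted p = 0.344 to 0.666). Within set P1117 the ribosomal and mitochondrial lists turned to lower (adjusted p = 0.827 and 0.460). Gluconeogenesis and growth factors and receptors did not pass there in intercalated cells, while fatty acid oxidation and unfolded protein response did. No gene of 7236 passed with edgeR, 1015 had an unadjusted p under 0.05 and DESeq2 called 17. Slc5a12 at 1.35 ± 0.22, Efcab5 at 1.40 ± 0.25 and G6pc at 1.42 ± 0.26 had the smallest p (adjusted p = 0.0730 each), with free RNA of proximal tubule not subtracted. Degs2 at −1.14 ± 0.22 and Plcz1 at 2.89 ± 0.58 followed. Of 15 proximal tubule markers 13 had a fold above 0 in intercalated cells (median 0.40, camera adjusted p = 0.00119, 0.495 with an estimated correlation). Thick ascending limb (−0.58) and principal cell markers (−0.43) were lower (adjusted p = 0.0337 and 0.0315). Those 2 marker calls were also lost with an estimated correlation (adjusted p = 0.416 and 0.495). Within set P1117 5 genes passed, Slc5a12 and Efcab5 among them (adjusted p = 0.0248 and 0.0317), and with the set as a term 4. Without 2-kidney replicate 1 there were 114, and without 1-kidney replicate 3 there were 6.

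In endothelial nuclei, unfolded protein response (median log2 fold 0.45, 15 of 17 above 0, camera adjusted p = 0.00169), glucocorticoid response (0.40, adjusted p = 0.00623), cell cycle (0.42), mitochondrial genome (0.22) and proximal tubule transport (0.27) rose as lists in the 1-kidney libraries, and angiogenesis and endothelium genes fell (−0.28, 4 of 22 above 0, adjusted p = 0.0476). These 6 were lost with an estimated correlation (adjusted p = 0.634 to 0.729), and within set P1117 the first 3 held (adjusted p = 0.00111 to 0.0056). The ephrin receptor gene Epha4 at −1.42 ± 0.25 (SE), Cyp4a8 at 1.18 ± 0.19, Chd1l at 1.23 ± 0.22, the sphingomyelin synthase gene Sgms2 at 1.44 ± 0.27 and G6pc at 1.66 ± 0.31 had the smallest p, none past the threshold (edgeR adjusted p = 0.0596 to 0.0724). Free RNA of proximal tubule was not subtracted, which bears on Cyp4a8 and G6pc. Fkbp5 stood at 1.36 ± 0.41 (adjusted p = 0.266). Of 15 proximal tubule markers 14 had a fold above 0 in endothelium (median 0.39, camera adjusted p = 0.000128, 0.529 with an estimated correlation). Cycling markers were higher (0.52, adjusted p = 0.0102) and the endothelial (−0.29) and thin limb markers (−0.48) lower (adjusted p = 0.0428 each). These 3 marker calls were also lost at 0.529. No gene of 7638 passed with edgeR, 800 had an unadjusted p under 0.05 and DESeq2 called 20. The count was 0 within set P1117 and 16 with the set as a term. Without 2-kidney replicate 1 there were 56, and without 1-kidney replicate 1 and 2-kidney replicates 2 and 4 there were 1, 5 and 9.

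**Figure D3:**
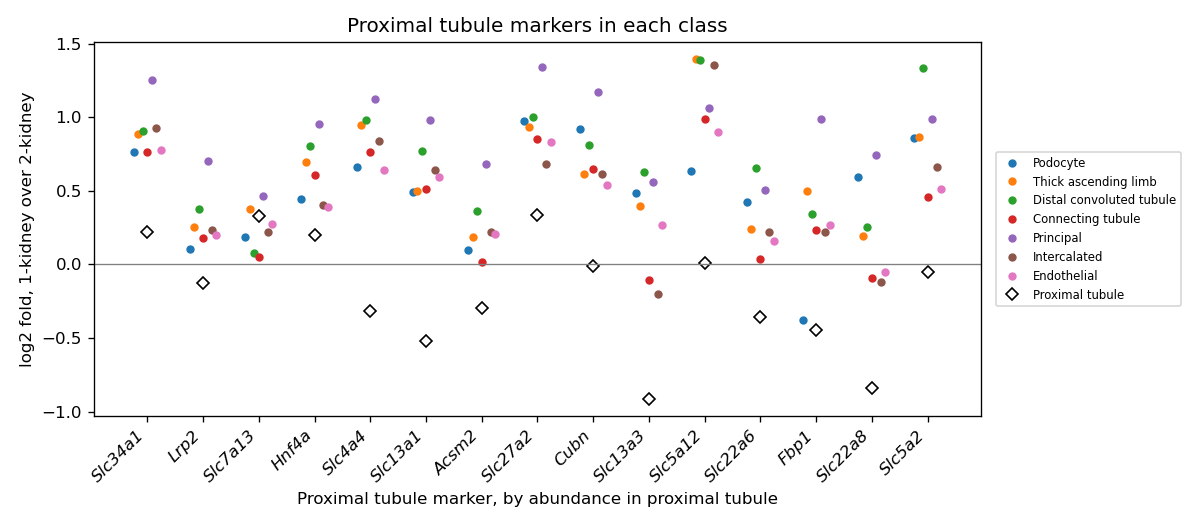
Log2 fold, 1-kidney over 2-kidney (vertical axis), of 15 proximal tubule markers (horizontal axis, by falling abundance in proximal tubule), 1 coloured point per other class and open diamonds for proximal tubule itself. Over the 7 other classes the median fold was above 0 for all 15 markers, while in proximal tubule the values lie on both sides of 0. Free RNA was not subtracted.

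Over the 9 comparisons, all retained nuclei and 8 classes, 245 list tests were made and 56 passed, 44 higher and 12 lower in the 1-kidney libraries. With an estimated correlation 0 passed (smallest adjusted p = 0.278). At the preset correlation glucocorticoid response passed as higher in all 9 comparisons, also within set P1117, and unfolded protein response in 7 (0.278 and 0.339 at the lowest with an estimated one). With fry 1 passed, growth factors and receptors in thick ascending limb (adjusted p = 0.0227). Fatty acid oxidation passed in 5 comparisons and gluconeogenesis in 2, neither in proximal tubule, with free RNA of proximal tubule not subtracted. Among the libraries of set P1117 fatty acid oxidation passed as higher in all 9 and gluconeogenesis in 0. Within set P1117 64 passed, 37 higher and 27 lower. Of the 56 calls 52 had the same direction there and 38 passed. The mitochondrial genome list passed as higher in 5 comparisons with all 7 libraries, but within set P1117 as higher in 0 and as lower in 3. Proximal tubule transport passed there as higher in 4 and as lower in 1, and antigen presentation as lower in 1. With all 7 libraries no comparison passed for tubular injury (smallest adjusted p = 0.244), nuclear-encoded oxidative phosphorylation (0.154), or glycolysis and hypoxia (0.475), nor for fatty acid synthesis (0.0809), amino acid stress and mTORC1 (0.594) and distal nephron and collecting duct transport (0.0800). The same holds for vasoactive genes (0.281), DNA methylation and chromatin (0.189), antioxidant and NRF2 (0.0729), interferon response (0.130), complement (0.569), circadian clock (0.413) and apoptosis and p53 (0.521). Within set P1117 some of these passed at the preset correlation, distal nephron and collecting duct transport as lower in 5 comparisons, oxidative phosphorylation as lower in 2, interferon response as lower in 1, and glycolysis and hypoxia and DNA methylation and chromatin as higher in 1 each. Of 85 tests of cell type markers 24 passed, none with an estimated correlation (smallest adjusted p = 0.110). Markers of connecting tubule (smallest adjusted p = 0.201), intercalated (0.0965), parietal epithelial (0.147), mural (0.451), macrophage and dendritic (0.101), T and NK (0.720) and lymphatic endothelial cells (0.962) passed in none.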

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

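In this part the test of parallel marker folds and its repeat over the splits, the test within set P1117, the test on gene abundance and the test with the Slc7a13 cluster alone were chosen only after the results they measure had been seen. A difference between groups of cells called for a closer look. In 33 of 10488 genes the 1-kidney effect differed between proximal tubule and thick ascending limb in a test of the difference itself, 30 with the lower effect in proximal tubule and 3 with the higher. The genes with the smallest p were Col27a1 (0.79 in proximal tubule and 2.68 in thick ascending limb), Slc6a19 (−0.36 and 1.06), Etv1 (−0.20 and 1.65) and Slc13a3 (−0.91 and 0.40). Over the 30 genes the median log2 fold was −0.60 in proximal tubule and 0.63 in thick ascending limb. Of the 35 splits of the 7 libraries into 3 and 4, 3 gave at least 33 genes, the real one included, so chance cannot be excluded. The highest other split gave 177 and the next 150, several times the real count, which points to a structure of the samples. The split with 177 sets 2-kidney replicates 2, 3 and 4 apart. It keeps both libraries of set P1117B together and all 1-kidney libraries as well, so it does not tell set from number of kidneys. Within set P1117 3 genes passed. In the 56 sets of 4 values of the 2-kidney libraries 0 passed Dixon's test, which cannot find 2 libraries that stand apart together, as those of set P1117B do (chi-square per gene of 83.6 to 144 to the other 5 libraries and 31.6 to each other), and the 1-kidney libraries were not tested this way.

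Proximal tubule transcripts were higher in the 7 other classes of the 1-kidney libraries, with a median log2 fold of 0.60 over 15 markers, while in proximal tubule nuclei the same markers had a median of −0.13. Set P1117B as the whole cause is argued against, since the median within set P1117 was 0.37 with 14 of 15 markers above 0. Free RNA of proximal tubule nuclei in the droplets stays open, since no test told it from a change of the cells. Of the genes with the lower effect in proximal tubule 93.3% were more abundant there, against 38.7% of all tested genes, which either would give. Marker folds ran in parallel between classes (median r 0.792), but the classes share their libraries. Of the 35 splits 4 gave an r at least as high, the real one included, with a median of 0.678 over the others. Drawn to equal numbers of nuclei in thick ascending limb, 1-kidney libraries held 299980 to 421904 UMIs and 2-kidney libraries 464073 to 598864. The groups were also apart in distal convoluted tubule, connecting tubule and intercalated cells. They overlapped in podocytes, proximal tubule, principal cells and endothelium. How far fewer UMIs per nucleus bear on the marker folds was not tested. More free RNA of an unchanged makeup is open too, because the 3 most abundant markers had a median of 0.38, between the bounds of 0.25 and 0.5 set beforehand, and Slc5a12 and Slc4a4 one of 0.97. A different mix of the 2 proximal tubule clusters is open for the lower effects in proximal tubule (median effect difference −0.40 with quartiles of −0.70 and −0.08 with the Slc7a13 cluster alone, −1.32 with the whole class). Whether that mix bears on the other classes through free RNA was not tested. Also open are undetected doublets, the make-up of the section and a change of these cells in 1-kidney animals, these 3 untested.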

How the results depend on the processing

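Chosen after seeing the data were sums over named clusters only, each proximal tubule cluster alone, shares among named nuclei and quality measures without set P1117B. All counts below are of genes past the threshold unless another unit is given, and the cause of a shift was not tested unless it is named.

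The count in all retained nuclei stayed at 0 with RLE factors, no low-count filter, the library set as a term, set P1117B left out, doublets kept, the 10% mitochondrial limit, equal nuclei and named clusters only, and was 475 with DESeq2. DESeq2 also gave 4 in podocytes, 115 in proximal tubule, 64 in thick ascending limb, 26 in distal convoluted tubule, 60 in connecting tubule, 208 in principal cells, 17 in intercalated cells, 20 in endothelium, and 77 and 33 in the Slc7a13 and Slc5a12 clusters. RLE factors gave 2 in podocytes and 1 in thick ascending limb and kept the counts of the other classes within 1.5 times. Without the low-count filter there were 66 in podocytes, 65 in proximal tubule, 196 in thick ascending limb, 121 in distal convoluted tubule, 158 in connecting tubule, 527 in principal cells, 145 in intercalated cells, 55 in endothelium, and 182 and 157 in the Slc7a13 and Slc5a12 clusters.

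The library set as a term gave 0 in podocytes, 11 in thick ascending limb, 0 in distal convoluted tubule, 0 in principal cells, 4 in intercalated cells, 16 in endothelium and 2 in the Slc7a13 cluster, and 16 in connecting tubule beside 15 without it. Without set P1117B, which leaves 3 libraries against 2, there were 0 in podocytes, 3 in proximal tubule, 15 in thick ascending limb, 5 in distal convoluted tubule, 29 in connecting tubule, 0 in principal cells, 5 in intercalated cells, 7 in the Slc7a13 cluster and 6 in the Slc5a12 cluster. Predicted doublets kept gave 3 in podocytes, 1 in thick ascending limb and 0 in principal cells. The 10% mitochondrial limit gave 6 in podocytes and 3 in endothelium. Equal numbers of nuclei gave 0 in podocytes, 6 in thick ascending limb, 0 in distal convoluted tubule and 40 in principal cells. Classes by marker score gave 2 in podocytes, 0 in thick ascending limb, 0 in distal convoluted tubule, 4 in connecting tubule and 0 in principal cells.

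Leaving out 1 library gave 0 to 143 in podocytes, 0 to 115 in thick ascending limb, 0 to 232 in distal convoluted tubule, 0 to 117 in connecting tubule, 0 to 142 in principal cells, 0 to 114 in intercalated cells and 0 to 56 in endothelium. The highest of these came without 2-kidney replicate 1, in connecting tubule without 2-kidney replicate 2. All retained nuclei, proximal tubule and its 2 clusters stayed at 0 without any 1 library. The effect that differs between proximal tubule and thick ascending limb had 0 to 169 genes without 1 library, 3 without set P1117B and 3 with the Slc7a13 cluster alone. List calls numbered 38 to 61 without 1 library, 53 with RLE factors, 64 without set P1117B, 0 with an estimated correlation and 1 with fry.

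Of the 37 changed genes named, none reversed. Where libraries were left out this was all but fixed, since the rule for naming required values that did not overlap between groups or the called genes had such values. Past the threshold were 35 of 37 with RLE factors, 35 of 35 measured with DESeq2, 37 of 37 without the filter, 30 of 37 at the 10% limit, 19 of 36 with doublets kept, 19 of 35 with equal nuclei, 9 of 37 with the set as a term, 11 of 37 without set P1117B and 2 of 37 with classes by marker score. Without 1-kidney replicates 1 to 3 in turn there were 3, 0 and 11 of 37, and without 2-kidney replicates 1 to 4 there were 37, 28, 1 and 27. Some uncalled genes near 0 in all retained nuclei changed sign. With the set as a term Kitlg was 0.0078 and Spp1 −0.056. Without set P1117B they were 0.0059 and −0.058, and with named clusters only Kitlg was 0.020 and Nphs1 0.059. Without 1 library Kitlg ranged from −0.19 to 0.042, Nphs1 from −0.29 to 0.19 and Spp1 from −0.28 to 0.22. Without set P1117B the mitochondrial genome list turned to lower in distal convoluted tubule (camera adjusted p = 0.202), connecting tubule (0.0417) and intercalated cells (0.460), and cytosolic ribosomal proteins in intercalated cells (0.827).

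No class share and no quality measure passed its threshold under any alternative run, and with a 2-kidney library left out the exact test allows no p below 0.1 and with a 1-kidney library none below 0.0667. The difference in mitochondrial share turned from 0.234 to −0.215 percentage points without set P1117B. Some differences in share, in percentage points, changed sign. Proximal tubule stood at −1.93, and at 1.33 by marker score and 3.67 at resolution 2. Macula densa stood at −0.0505, and at 0.931 by marker score, 0.0147 when centred within library, 0.117 without set P1117B and 0.0181 among named nuclei. Mural cells stood at −0.0378 with doublets kept and −0.0153 at the 10% limit. Without 1 library thick ascending limb ranged from −2.63 to 0.405, macula densa from −0.185 to 0.0831, principal cells from −1.98 to 0.0617, mural cells from −0.0460 to 0.0338 and macrophages from −0.0954 to 0.517.

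A Y-linked covariate was planned for libraries that differ in it and was not run, since Kdm5d and Eif2s3y lay at like levels in all 7. Subtraction of ambient RNA, batch integration and other doublet callers were also not run. Recovery of simulated changes was lowest in principal cells, 12% of 2-fold and 78% of 4-fold ones, for a cause that was not tested.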

Other observations

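In this part the test of the glucocorticoid list within set P1117, the repeated thinning and the test of the shared set were chosen only after the results they measure had been seen, and the verdict on depth for 2-kidney replicate 1 was first left open after its value was seen and then set by the repeated thinning. Glucocorticoid response genes were higher as a list in all 9 comparisons with the preset correlation and in 0 with an estimated one, with a median over the comparisons of 0.60 on the log2 scale. Set P1117B as the whole cause is argued against by a median of 0.51 within set P1117, although the value in thick ascending limb there was 0.17. A single 1-kidney library as the cause is argued against too, since leaving out each of the 3 gave a median of at least 0.53, with 0.20 in podocytes without 1-kidney replicate 2 as the lowest single value. This median was not computed with a 2-kidney library left out, so a single 2-kidney library as the cause stays open. The 9 comparisons are not independent, since all use the same 7 libraries and all retained nuclei contain the classes. Free RNA also spreads transcripts of 1 class over all droplets, and it was not tested for this list. Handling before death, the hour of sampling and a hormonal difference of the 1-kidney animals stay open and untested, so a higher glucocorticoid signal in these animals is a hypothesis only.

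2-kidney replicate 1 lay closer to the 1-kidney libraries than 2-kidney replicates 2 and 4 with the classes pooled, a pattern seen from the counts of genes with it left out (232 in distal convoluted tubule against 14 with it) and from the other splits. Over the 882 genes called without it in the 8 classes, its median position was 0.602 on a scale from the 2-kidney mean at 0 to the 1-kidney mean at 1 (quartiles 0.309 and 0.843), against 0.489 for 2-kidney replicate 2 and 0.205 for replicate 4 on the genes called without them, with the order reversed in connecting tubule (0.456 over 80 genes against 0.528 over 117 for replicate 2) and close values in principal cells (0.476 and 0.464). These gene sets differ, and the 1-kidney libraries left out also lay near the middle (0.544 over 34 genes for replicate 3, 0.507 over 4 for replicate 1, 0.497 over 1 for replicate 2, with 2-kidney replicate 3 at −0.56 over 1), so the scale parts the groups poorly and a wrong label cannot be told apart from the set or from an animal between the groups, with 0.602 between the bounds of 0.5 and 0.8 set beforehand. A lower UMI total per class as the whole cause is argued against. In 5 classes the split that moves this library to the 1-kidney side called more genes than the real split before thinning (77 against 3 in thick ascending limb). Of these, 4 did so in each of 10 draws thinned to equal UMI totals (95 against 5 in the first draw). The bound set beforehand against depth, at least 4 of 8 classes, was met with 4 by the first draw and by the lowest of the 10. The thinning left UMIs per nucleus as they were, so fewer UMIs per nucleus stay open as a cause. Their median was 1883.5 in 2-kidney replicate 1. It was 1445 to 1965 in the 1-kidney libraries and 2173 to 2506.5 in the other 2-kidney libraries. The set shared with the 1-kidney libraries is a candidate explanation, since set P1117B makes up 2 of the 3 other 2-kidney libraries. Over 10896 genes, summed over the classes, called between the 1-kidney libraries and set P1117B, replicate 2 had a median position of 0.671 beside 0.766 for 2-kidney replicate 1. This pooled gap is just under the 0.1 allowed, a bound written after the results had been seen, with replicate 1 higher in all 8 classes. Both libraries were left out when these genes were chosen. That choice favours genes that differ by set and draws libraries left out toward the middle, so these positions do not show the set to be the cause. The gap was wider than 0.1 in podocytes (0.842 for replicate 1 and 0.546 for replicate 2), thick ascending limb (0.779 and 0.630), distal convoluted tubule (0.779 and 0.638) and intercalated cells (0.782 and 0.667). It was under 0.1 in proximal tubule, connecting tubule, principal cells and endothelium. Differences between animals were not tested.

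Other splits of the 7 libraries were run for every count of changed genes. The real split gave 0 genes in all retained nuclei, 0 in proximal tubule, 0 in intercalated cells and 0 in endothelium with edgeR (3082, 1822, 1015 and 800 at an unadjusted p under 0.05, and 475, 115, 17 and 20 with DESeq2), a count that all 35 splits reach, and the highest others gave 2, 16, 220 and 34. In podocytes the real count was 1 and the highest other 162, in thick ascending limb 3 and 77, in distal convoluted tubule 14 and 271, in connecting tubule 15 and 67, and in principal cells 17 and 36. In each of these 5 classes 2 of the 35 splits gave at least the real count, the real one included, so chance cannot be excluded. For gene lists the real count was 56, 4 of 35 splits gave as many, and the highest other gave 66, so chance cannot be excluded there either.

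In podocytes, thick ascending limb, distal convoluted tubule and connecting tubule the highest split gave several times the real count, which points to a structure of the samples. In podocytes, thick ascending limb, distal convoluted tubule, intercalated cells and endothelium the highest split set 2-kidney replicates 2, 3 and 4 apart. In all retained nuclei, proximal tubule, connecting tubule and principal cells it set 2-kidney replicates 1, 3 and 4 apart. Both keep the 2 libraries of set P1117B together. Both also keep the 3 libraries of the 1-kidney group together, so each is the real split with 1 library moved. The next highest other split gave 0 genes in podocytes, thick ascending limb, connecting tubule and principal cells, and 2 in distal convoluted tubule. Splits that joined set P1117B with a 1-kidney library thus gave few or no genes in these classes. Within set P1117 the real comparison gave 0 genes in all retained nuclei, 0 in podocytes, 3 in proximal tubule, 15 in thick ascending limb, 5 in distal convoluted tubule, 29 in connecting tubule, 0 in principal cells, 5 in intercalated cells and 0 in endothelium.

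Slc34a1 made up 2.72%, 3.42% and 3.02% of the UMIs of 1-kidney replicates 1 to 3 and from 1.17% in replicate 4 to 2.54% in replicate 1 of the 2-kidney libraries. The transcript AC134224.3 made up 4.04%, 4.04% and 4.18% of UMIs in the 1-kidney and 4.22%, 4.06%, 3.33% and 3.47% in the 2-kidney replicates. Among the unnamed clusters, 1 of 159 nuclei was led by the urothelial genes Upk1a and Upk1b, and 1 of 105 nuclei by Fth1 and ribosomal protein genes.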
